A study of Mus musculus with 14 samples.

How the data were processed

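Gene expression was measured on Affymetrix 3' arrays in sorted mouse bone marrow cells. The 14 arrays fall into 6 groups by their titles. Pax5KO engrafted and WT engrafted cells (3 arrays each) came from fetal liver of day 15 embryos, either without Pax5 or wild type, that carried a reporter for λ5, a surrogate light chain. The donor cells had been put into irradiated mice, and the marrow cells positive for B220 and for the reporter were sorted after 4 weeks. Ly6D- CLP, Ly6D+ CLP, ProB and PreB cells (2 arrays each) were sorted from mice that received no transplant; CLP stands for common lymphoid progenitor. The mice were C57Bl6 of 8 to 12 weeks. Sort gates of the cells without transplant, beyond the names of the groups, are not stated in the labels. The PreB arrays carry the replicate numbers 2 and 3 in their titles and 1 and 2 in their descriptions; the title numbers name the arrays here, and the description numbers pair PreB with ProB for the replicate block.

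The deposited table gives 1 log2 signal per probe set and array, for 45101 probe sets. Per the submitters' processing notes, RMA, GCRMA and limma were used; which of them made the table, and their versions, are not stated. The values run from 2.32 to 16.1 and share a floor at the lowest value, which 31.3% to 36.8% of the probe sets of each array held. Array medians lay between 2.41 and 2.52 and upper quartiles between 5.39 and 5.98, so the table was taken as already scaled between arrays. No detection call was used here. A difference from a group at the floor is therefore a lower bound of the change in transcript level, and no fold is given where both groups are at the floor. A group counted as at the floor when each of its arrays lay within 0.5 of the lowest value. The number of arrays limits the precision of each value.

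Gene names came from the platform's annotation, updated through the RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none here and 64 were controls; 34741 of those with 1 symbol were matched in the RefSeq table. Each gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. None of the genes named by rule had a probe set called in the opposite direction. For some, only 1 of several probe sets was called, as for Socs2 (1 of 6) between the engrafted groups. The same held for Igll1 (1 of 2) from Ly6D- to Ly6D+ CLP, Ighg3 (1 of 4) from Ly6D+ CLP to ProB, and Id2 (1 of 3) from ProB to PreB. For others all were called, such as Fcrla (3 of 3) between the engrafted groups. Probe sets with several symbols or none were left out of the comparisons.

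Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean per group and all 14 arrays in a single fit, which leaves 8 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes, and genes with an adjusted p under 0.05 were called, with no minimum fold. Pax5KO engrafted cells were compared with WT engrafted cells, Ly6D+ with Ly6D- CLP, ProB with Ly6D+ CLP and PreB with ProB. Changes are given as log2 differences with the standard error (SE) of the fit, and group means with the standard deviation (SD) over arrays.

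Before the data were examined, 19 gene lists were written from general knowledge: early B lineage and pre-B receptor, genes described as activated by Pax5, genes described as repressed by Pax5, pre-B and light chain stage, B cell maturation and antigen presentation, T lineage, NK and innate lymphoid, granulocyte and monocyte, dendritic, erythroid and megakaryocyte, stem and multipotent progenitor, plasma cell, cell cycle, IL-7 and cytokine signalling, glucose uptake and glycolysis, interferon response, immediate early and stress, ribosomal proteins, and stromal and endothelial. Of their 408 entries, 366 were measured, and a gene can stand in several lists. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 19 lists and called under 0.05. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, were run as alternatives. A count called "adjusted over the list alone" repeats the Benjamini-Hochberg adjustment within the list.

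Stage lists were made from the cells without transplant. They held the 100 genes with the largest rise and the 100 with the largest fall among the genes called at each of the 3 steps, and were tested in the comparison of engrafted cells with camera, adjusted over the 6 lists. A stage score per array was the mean of the rise list minus the mean of the fall list of the step from Ly6D+ CLP to ProB. It was compared between the engrafted groups by an exact two-sided permutation test, whose smallest p is 0.1 for 3 arrays against 3.

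The genes to be named were fixed by rule before the data were examined. Of the genes analysed here, these were in each comparison Pax5, Igll1, which encodes λ5, Ly6d, and Ptprc, which encodes B220; the 6 largest rises and 6 largest falls among called genes whose groups do not overlap in any array; and the 2 members of each list with the largest change, called or not. Called list members named beyond these, to complete a count of 5 or fewer, were chosen after their values were seen.

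The scripts were tested on simulated data with independent normal noise of each gene's residual SD, without correlation between genes. In each comparison, 50 genes with a mean above 5 were raised or lowered by each of 4 sizes among 18193 genes. The recovered shares do not cover genes near the floor. In the comparison of engrafted cells, 10%, 50%, 78% and 86% of the genes with a log2 change of 1, 2, 3 and 4 were recovered, and 11 of 123 calls were false. For Ly6D+ against Ly6D- CLP, the recovered shares were 12%, 42%, 56% and 82%, with 14 of 110 calls false. For ProB against Ly6D+ CLP they were 4%, 32%, 64% and 74%, with 17 of 104 calls false. For PreB against ProB they were 0%, 40%, 60% and 72%, with 8 of 94 calls false. The false share thus exceeded 5% in each simulated comparison, and most changes of 1 on the log2 scale were not recovered.

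Across the 7548 genes with a mean above 5, the deviations of same-numbered Pax5KO and WT engrafted arrays from their group means correlated with r of 0.18, 0.36 and 0.61; the r is across genes, which are not independent replicates. This check of the values did not pair all engrafted arrays by number. Pax5KO array 1 correlated best with WT array 2 (r = 0.46). Pax5KO array 2 correlated with WT array 2 (r = 0.36) and also with WT array 1 (r = 0.26). Only the pair with r of 0.61 stood apart, since both its arrays correlated negatively with the remaining arrays of the other genotype. Deviations within a group cancel out, so these r depend on each other. The labels name no shared litter or day. A fit with the number as a block was an alternative. Correlations between arrays of a group lay between 0.938 and 0.989, and the highest between arrays of different groups was 0.963.

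The alternatives, planned before the data were examined unless stated, were a fit to the arrays of the compared groups only, a trended and robust variance prior, the mean of all probe sets of a gene, each probe set tested on its own, leaving out genes under the 40th percentile, equal array medians, quantile normalization, array weights, a minimum change of 2-fold, the replicate block, and each array left out in turn. Stage lists were also made with 50 genes, with all called genes and without the cell cycle list. Leaving out genes at the floor and leaving out both engrafted arrays numbered 3 were added after the data were seen. So were a term for arrays with high Xist (above 7) and stage lists without genes of other cell types. Xist varied within the WT engrafted group alone, so the term was set in every comparison by WT array 3 against the other WT arrays. Between the engrafted groups it leaves the Pax5KO mean against WT array 3.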

Results

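The series held 14 arrays of early B lineage cells and their progenitors: 3 of Pax5KO engrafted cells, 3 of WT engrafted cells, and 2 each of Ly6D- CLP, Ly6D+ CLP, ProB and PreB cells. Pax5, the transcription factor that commits lymphoid progenitors to the B lineage and the gene removed in the knockout donors, was read by 2 probe sets. The brighter of them read between 7.57 and 7.95 on the Pax5KO arrays and between 6.18 and 6.76 on the WT engrafted arrays. It read 2.83 and 3.03 in Ly6D- CLP, 3.41 and 6.17 in Ly6D+ CLP, 3.92 and 4.90 in ProB, and 5.01 on both PreB arrays. The labels do not say which part of Pax5 is deleted; a probe set outside the deleted part checks nothing, so these values do not test the genotype.

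The comparison of Pax5KO with WT engrafted cells asked how the transcripts of B220+ λ5 reporter+ marrow cells differ when the donor cells lack Pax5. Fcrla, an Fc receptor-like protein of B cells, read 2.66 ± 0.20 (SD, n = 3) in Pax5KO and 12.27 ± 0.39 (SD, n = 3) in WT cells and fell by 9.61 on the log2 scale (SE 0.28, limma adjusted p = 4.3e-07). Ms4a1, which encodes CD20, fell by 9.21 (SE 0.37), Cd72, an inhibitory co-receptor, fell by 9.17 (SE 0.35), and Fcmr, the Fc receptor for IgM, fell by 8.48 (SE 0.22). Scd1, a fatty acid desaturase, fell by 8.28 (SE 0.37) and Srpk3, a kinase of splicing factors, fell by 8.17 (SE 0.92). The limma adjusted p of these genes lay between 2.83e-07 and 0.00111.

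The largest rises in Pax5KO cells were those of Myl10, a myosin light chain, Ffar2, a receptor for short-chain fatty acids, and Adgrg3, an adhesion receptor. Myl10 read 10.93 ± 0.65 (SD, n = 3) against 3.22 ± 0.56 (SD, n = 3), a rise of 7.71 (SE 0.46, limma adjusted p = 3.16e-05). Ffar2 rose by 7.50 (SE 0.62), Adgrg3 by 7.26 (SE 0.55), ccdc198 by 7.11 (SE 0.45) and Bex6 by 6.74 (SE 0.70). Jchain, which joins IgA and IgM into polymers, rose by 6.90 (SE 1.44, limma adjusted p = 0.0253). The Jchain call ended without Pax5KO array 1, 2 or 3 or WT array 1 or 2, with limma adjusted p of 0.0789, 0.0809, 0.0748, 0.0889 and 0.0516 and changes between 5.76 and 7.43. Flt3, a growth factor receptor of early progenitors, rose from 3.56 ± 0.15 to 9.46 ± 0.65 (SD, n = 3 each), by 5.90 (SE 0.33, limma adjusted p = 2.23e-05). Of the genes used for sorting, Igll1, which encodes λ5, read 12.88 in Pax5KO and 11.98 in WT cells (difference 0.90, SE 0.36, limma adjusted p = 0.251) and was called without WT array 3 (1.29, limma adjusted p = 0.0418). Ptprc, which encodes B220, differed by -0.64 (SE 0.45, limma adjusted p = 0.692), Ly6d, a surface marker of B-directed progenitors, by -1.05 (SE 0.45, limma adjusted p = 0.310), and Pax5 itself by 1.30 (SE 0.60, limma adjusted p = 0.367). The dimmer Pax5 probe set read 2.33 ± 0.01 in Pax5KO and 3.08 ± 0.56 in WT cells (SD, n = 3 each), a difference of -0.75 (SE 0.44, limma adjusted p = 0.669).

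**Figure D1:**
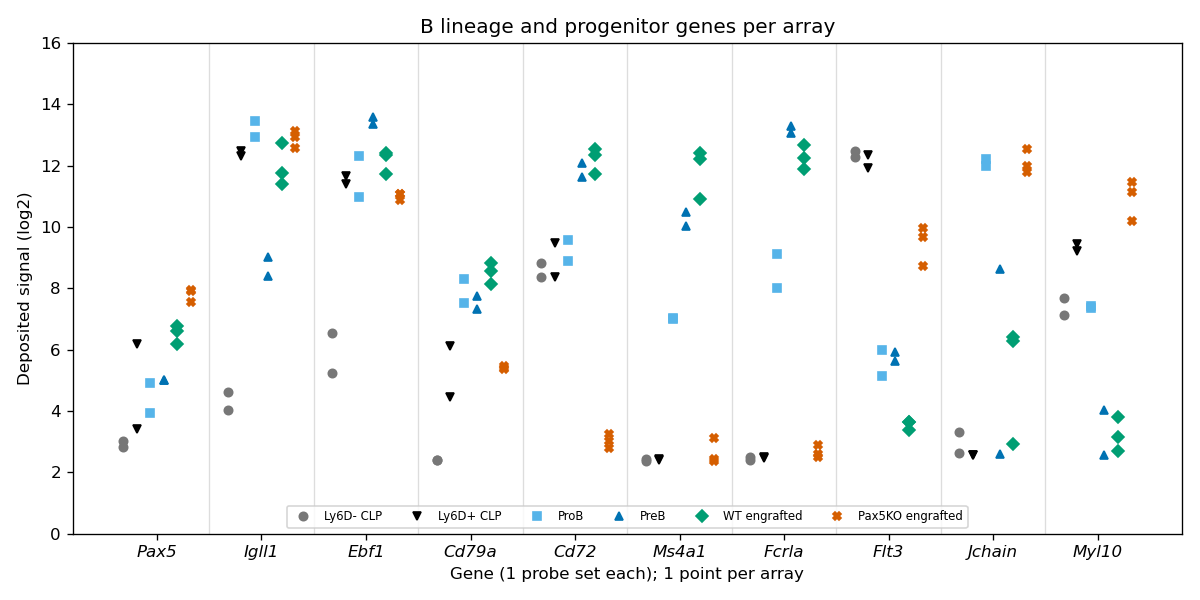
Deposited log2 signal (vertical axis) of 10 genes (horizontal axis), with 1 point per array and a symbol per group. Fcrla read between 2.49 and 2.88 on the Pax5KO arrays and between 11.88 and 12.67 on the WT engrafted arrays.

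Of 18193 genes, 1080 were called, 663 higher and 417 lower in Pax5KO cells. An unadjusted p under 0.05 was found for 2760, and 2 of the called genes were at the floor in both groups. Xist varied only within the WT group. A term for arrays with high Xist therefore leaves the Pax5KO mean against WT array 3 alone. Under that term the larger share of calls changed sides. The count was 697 when only the 6 engrafted arrays were fitted, 3065 with array weights, 676 without Pax5KO array 1 and 718 without WT array 1. Xist, the X-inactivation transcript, was above 12 on the 3 Pax5KO arrays and WT array 3 and below 3 on WT arrays 1 and 2, so the genotype and the sex of the cells overlap in part. The actin probe sets differed more between the 3' and 5' ends on each Pax5KO array than on the WT array of the same number. The values were 3.16 against 2.51, 3.14 against 2.56 and 4.57 against 3.47. The same held for Gapdh (3.90 against 2.61, 3.17 against 3.02 and 5.79 against 5.44). The numbers need not pair the arrays, though, and WT array 3 lay above Pax5KO arrays 1 and 2 for both genes. This measure of RNA quality thus also overlaps in part with the genotype.

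Of 27 measured genes described as activated by Pax5, 19 fell and none rose (camera adjusted p = 2.51e-37, limma); adjusted over the list alone, 24 fell. They included Cd72 and Srpk3. Of 16 genes described as repressed by Pax5, 7 rose and none fell (camera adjusted p = 8.69e-05), among them Flt3 and Jchain, and 7 rose and 1 fell adjusted over the list alone. Both lists, the pre-B list and the B cell maturation list also passed with an estimated correlation, at adjusted p between 0.00245 and 0.00899.

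Of 17 pre-B and light chain genes, 10 fell and none rose (camera adjusted p = 3.28e-20); adjusted over the list alone, 13 fell. Cd2, an adhesion receptor, read at the floor in Pax5KO cells and 8.78 ± 0.74 (SD, n = 3) in WT cells, and fell by 6.43 (SE 0.30, limma adjusted p = 7.34e-06). Of 19 genes of B cell maturation and antigen presentation, 12 fell and none rose (camera adjusted p = 1.62e-23), led by Ms4a1 and Fcmr; adjusted over the list alone, 15 fell. In the early B lineage and pre-B receptor list of 26 genes, 8 fell and 2 rose, and 12 fell and 2 rose adjusted over the list alone (camera adjusted p = 4e-06; adjusted p = 0.13 with an estimated correlation). The falls included Fcrla and Ikzf3, the lymphoid transcription factor Aiolos, which fell by 5.83 (SE 0.27, limma adjusted p = 6.18e-06). The rises were Cd93, a surface marker of immature B cells, by 2.14 and Dntt, the terminal transferase of gene segment joining, by 2.89.

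Of 20 stem and multipotent progenitor genes, 5 rose and none fell in Pax5KO cells: Flt3, Egfl7, Cd27, Kit and Lmo2. Egfl7, a secreted factor, rose by 4.68 (SE 0.36, limma adjusted p = 0.000122). Adjusted over the list alone, 9 rose and 1 fell (camera adjusted p = 0.000168; adjusted p = 0.0580 with an estimated correlation). Of 16 NK and innate lymphoid genes, Il18r1, Klrd1 and Id2 rose and none fell (camera adjusted p = 0.0225; adjusted p = 0.166 with an estimated correlation, and 0.0788 without Pax5KO array 3); 4 rose adjusted over the list alone. Il18r1, a receptor for interleukin-18, rose by 4.39 (SE 0.50, limma adjusted p = 0.00116) and Klrd1, the NK receptor CD94, by 3.33 (SE 0.39, limma adjusted p = 0.00137). Of 15 dendritic cell genes, Flt3, Tlr7 and Bst2 rose and Irf8 fell; adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.0245; adjusted p = 0.103 with an estimated correlation, 0.0788 without Pax5KO array 3 and 0.0507 without WT array 2). Tlr7, a receptor for RNA, rose by 3.46 (SE 0.40, limma adjusted p = 0.0014), and by 1.38 with an adjusted p of 0.274 when its probe sets were averaged.

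In the plasma cell list of 10 genes, Jchain rose and Ell2, Irf4 and Sdc1 fell, also adjusted over the list alone (camera adjusted p = 0.0328; adjusted p = 0.120 with an estimated correlation). The list call ended with averaged probe sets (adjusted p = 0.0635), without Pax5KO array 1 or 2 (0.0535 and 0.0570) and without WT array 2 (0.0759). Ell2, an elongation factor, fell by 4.56 (SE 0.83, limma adjusted p = 0.0133; 0.0564 without WT array 1 and 0.0516 without WT array 2). Of 37 cell cycle genes, Mcm6 rose and Ccna2 and Rrm2 fell; adjusted over the list alone, 1 rose and 3 fell (camera adjusted p = 0.000899; adjusted p = 0.281 with an estimated correlation and 0.119 by fry). Ccna2, which encodes cyclin A2, fell by 1.16 (SE 0.26, limma adjusted p = 0.0382). Its call ended when 1 array other than Pax5KO array 2 was left out, with adjusted p from 0.0727 to 0.137. E2f8, a cell cycle repressor, differed by -1.20 (SE 0.38, limma adjusted p = 0.133).

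Of 16 genes of glucose uptake and glycolysis, Hk2 and Slc2a3 rose (3 adjusted over the list alone; camera adjusted p = 0.0235; adjusted p = 0.121 with an estimated correlation, 0.0678 without dim genes and 0.0537 without Pax5KO array 1). Slc2a3, a glucose transporter, rose by 1.77 (SE 0.28, limma adjusted p = 0.0066). Of 18 interferon response genes, Rtp4 and Bst2 rose and none fell, and 6 rose adjusted over the list alone (camera adjusted p = 0.00642; adjusted p = 0.167 with an estimated correlation and 0.0645 without WT array 3). Rtp4 rose by 2.36 (SE 0.43, limma adjusted p = 0.0129; 0.0568 without Pax5KO array 1 and 0.0523 without Pax5KO array 2). Of 18 ribosomal protein genes none was called, over all genes or adjusted over the list alone, although the list passed camera upward (adjusted p = 0.0235; adjusted p = 0.378 with an estimated correlation, 0.167 by fry, 0.117 without dim genes, 0.112 without Pax5KO array 3 and 0.184 without WT array 2). Its largest difference was that of Rpl14 at 1.52 (SE 0.49, limma adjusted p = 0.139; 0.0432 with the replicate block and 0.00623 without WT array 3).

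The remaining 6 lists did not pass camera in this comparison. Of 17 genes of IL-7 and cytokine signalling, 5 rose, namely Socs2, Cish, Myc, Ccnd2 and Jak3, and Bcl2l1 and Pim2 fell (camera adjusted p = 0.269; 5 and 3 adjusted over the list alone). Socs2 and Cish, feedback inhibitors of cytokine receptors, rose by 3.55 (SE 0.63) and 3.13 (SE 0.42); the Socs2 call ended without Pax5KO array 1 (limma adjusted p = 0.0521). Of 20 immediate early and stress genes, Klf2, Btg2 and Jund fell and Ier2 rose (camera adjusted p = 0.0724; 4 fell and 1 rose adjusted over the list alone). The list was called without Pax5KO array 3 (adjusted p = 0.00897), without WT array 3 (adjusted p = 0.0336) and by fry (adjusted p = 0.0136). Klf2, a transcription factor of resting lymphocytes, fell by 6.62 (SE 0.39, limma adjusted p = 2.73e-05) and Btg2, an antiproliferative factor, fell by 3.02 (SE 0.33). Of 19 T lineage genes, Notch1, Cd247 and Lat rose and Dtx1, a Notch pathway gene, fell by 4.43 (SE 0.19), with the same counts adjusted over the list alone (camera adjusted p = 0.255). Of 23 granulocyte and monocyte genes, Fcer1g and Lyz2 rose, also adjusted over the list alone (camera adjusted p = 0.393). Lyz2, a lysozyme, rose by 2.52 (SE 0.49, limma adjusted p = 0.0179), with a call that ended without Pax5KO array 2 or 3 or WT array 1 or 2 (adjusted p from 0.0523 to 0.0680). S100a8, a granulocyte transcript, was between 4.59 and 6.25 on the Pax5KO and between 7.27 and 8.25 on the WT engrafted arrays. Of 16 erythroid and megakaryocyte genes, Car2 rose by 2.53 (SE 0.49) and Tfrc, the transferrin receptor, fell by 1.37 (SE 0.27), also adjusted over the list alone (camera adjusted p = 0.326). The Car2 call ended without Pax5KO or WT array 1 or 2, and that of Tfrc without Pax5KO array 2 or 3 or WT array 1 or 2, at adjusted p from 0.0640 to 0.0839 over both genes. Of 16 stromal and endothelial genes none was called, over all genes or adjusted over the list alone (camera adjusted p = 0.186). Its members Cxcl12 and Pecam1 differed by -1.09 (limma adjusted p = 0.161; 0.0270 without WT array 3) and -1.07 (limma adjusted p = 0.455; 0.0395 with the replicate block).

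Among list members with the largest differences, Ctsg, a granulocyte protease (2.56, limma adjusted p = 0.118), Ifih1, an RNA sensor (2.10, limma adjusted p = 0.133), Pfkl (1.83, limma adjusted p = 0.0562) and Rps6 (0.83, limma adjusted p = 0.374) were not called. Array weights called each of these 4 genes and also Pax5 (1.41), Igll1 (1.04) and Ly6d (-1.13), at limma adjusted p of 0.00930, 0.0168 and 0.0133. They also called Rpl14, Cxcl12 and E2f8 (0.00485, 0.0158 and 0.0267). Without dim genes Ctsg (0.0453) and Pfkl (0.0210) were called, and without genes at the floor Ctsg (0.0396), Ifih1 (0.0479) and Pfkl (0.0189). Equal array medians called Pfkl (0.0410) as well. With a term for arrays with high Xist, the calls of Jchain (0.265), Socs2 (0.0573), Car2 (0.220), Lyz2 (0.134), Slc2a3 (0.0545), Ccna2 (0.295), Tfrc (0.220) and Ell2 (0.168) ended, with the limma adjusted p in parentheses. In that order, the changes under the term were 5.69 (SE 2.08), 3.99 (SE 0.92), 2.04 (SE 0.70), 1.29 (SE 0.38), 1.83 (SE 0.42), -1.03 (SE 0.39), -1.16 (SE 0.40) and -3.79 (SE 1.19). These changes are those of the Pax5KO mean from WT array 3 alone. Lyz2 was at 51.3% of its change without the term, and the other 7 were at 80.7% to 112%. The SE of these 7 was at least 1.42 times as large. Without both arrays numbered 3, the calls of Jchain, Socs2, Ccna2, Tfrc and Ell2 ended (0.0663 to 0.172), as did that of the dendritic list (0.0644), while Rpl14 (0.0163) and the immediate early list (0.00193) were called. With only the 6 engrafted arrays in the fit, those of Jchain (0.0593), Car2 (0.115), Lyz2 (0.162), Rtp4 (0.143), Ccna2 (0.0981) and Tfrc (0.0699) ended. Without genes at the floor, the glycolysis (0.0652) and ribosomal (0.127) lists were not called. The Tfrc call also ended with averaged probe sets (0.384) and that of Ccna2 for single probe sets (0.0517).

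**Figure D2:**
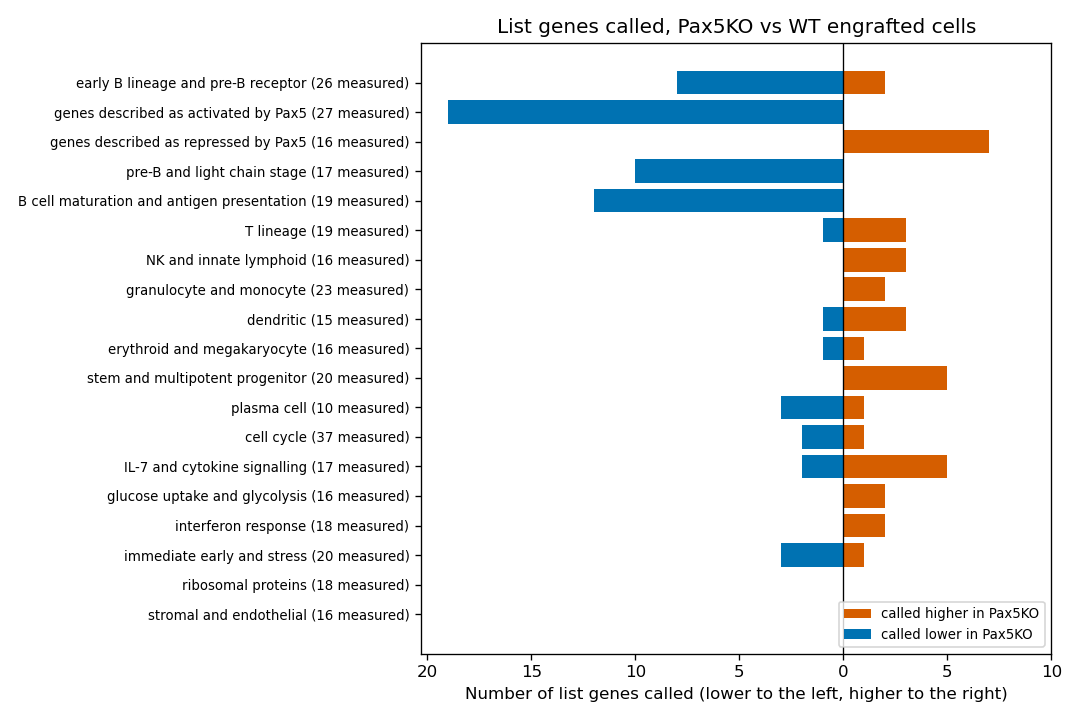
Number of genes of each of the 19 lists (vertical axis) called lower (bars to the left) and higher (bars to the right) in Pax5KO than in WT engrafted cells. The longest bar is that of the genes described as activated by Pax5, with 19 of 27 lower.

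Genes that changed most at the wild type steps were then compared between the engrafted groups. The comparison asked where along these steps the knockout and wild type cells differ. The lists also held granulocyte and antibody transcripts, such as S100a8 and Igha, to which other cell types in the sorted samples may have contributed. Those of the steps to ProB and PreB can also follow the sex of the cells. Of the 100 genes that rose most from Ly6D+ CLP to ProB, 42 were lower and 1 higher in Pax5KO cells, with a median difference of -1.04 (camera adjusted p = 1.72e-29, limma); Fcrla, Ms4a1, Scd1 and Srpk3 were among them. Of the 100 that fell most at that step, 50 were higher and 2 lower (median 2.05, camera adjusted p = 6.28e-31), Flt3 and Adgrg3 included. Of the 100 that rose most from ProB to PreB, 32 were lower and 6 higher (median -1.03, camera adjusted p = 2.56e-18), such as Cd2 and Klf2. Of the 100 that fell most there, 26 were higher and 2 lower (median 1.02, camera adjusted p = 6.64e-17), Myl10 and Jchain included. These 4 lists also passed with an estimated correlation, at adjusted p between 1.24e-05 and 0.0101. They were also called without genes of other cell types, antibody genes and sex-linked transcripts such as Xist. Of the genes that rose from Ly6D- to Ly6D+ CLP, 19 were higher and 16 lower (camera adjusted p = 0.559). Of those that fell there, 11 were higher and 3 lower (camera adjusted p = 0.0535; 0.0266 with an estimated correlation, 0.0295 without Pax5KO array 1 and 0.0475 without Pax5KO array 2).

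The stage score was -1.29 ± 0.14 (SD, n = 3) in Pax5KO and 2.72 ± 0.13 (SD, n = 3) in WT engrafted cells, a difference of -4.02 (exact two-sided permutation p = 0.1, the smallest this design allows). The difference was -5.29 with 50 genes per list and -1.63 with all called genes in the lists. It was -4.05 without genes of other cell types, antibody genes and sex-linked transcripts such as Xist. Each had the same p. The means of the score were -4.57 in Ly6D- CLP, -5.05 in Ly6D+ CLP, 3.84 in ProB and 2.0 in PreB, from the same arrays that gave the lists. Across 18193 genes, which are not independent replicates, the differences between Pax5KO and WT engrafted cells correlated with those of the 3 steps with r of 0.01, -0.32 and -0.39, in order.

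**Figure D3:**
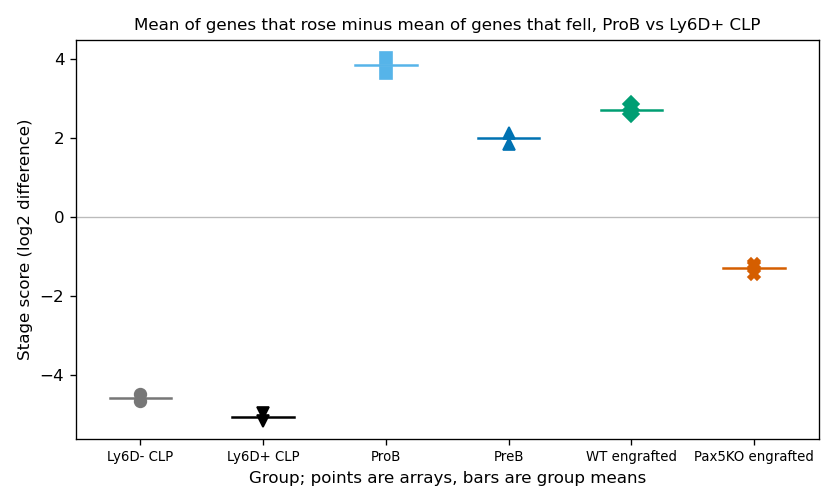
Stage score in log2 units (vertical axis) for each array, by group (horizontal axis), with a bar at each group mean. The Pax5KO engrafted arrays lie between -1.45 and -1.20, and the WT engrafted arrays between 2.60 and 2.87.

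The comparison of Ly6D+ with Ly6D- CLP followed the first step named in the titles. Pax5 read 4.79 ± 1.96 in Ly6D+ and 2.93 ± 0.15 (SD, n = 2 each) in Ly6D- CLP (difference 1.86, SE 0.73, limma adjusted p = 0.418), and was called without Ly6D+ array 2 (3.24, adjusted p = 0.00271). Vpreb1 and Igll1, which encode the surrogate light chain, rose by 8.24 (SE 0.48, limma adjusted p = 7.92e-05) and 8.07 (SE 0.44, limma adjusted p = 5.27e-05). Pou2af1, a coactivator of B cells, rose from the floor to 10.39 ± 0.15 (SD, n = 2), by 7.92 (SE 0.24, limma adjusted p = 1.01e-06). Ly6d, the marker used for the sort, rose from 3.31 ± 0.42 to 10.78 ± 0.67 (SD, n = 2 each), by 7.46 (SE 0.55, limma adjusted p = 0.00031). Gfra2, a receptor for GDNF family ligands, rose by 7.63 (SE 0.53) and Gpat3, an acyltransferase of lipid synthesis, by 6.33 (SE 0.41). The largest falls were those of Wfdc17 (-6.03, SE 0.34), Ddx4, an RNA helicase (-4.98, SE 0.48), Rab38, a small GTPase (-4.75, SE 0.42), Sh2b2, an adaptor protein (-4.62, SE 0.79), Cpq (-4.48, SE 0.27) and Hsd3b7 (-4.48, SE 0.53). The Sh2b2 call ended without Ly6D+ array 2 (limma adjusted p = 0.0728). Ptprc differed by -0.28 (SE 0.55, limma adjusted p = 1).

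Of 18193 genes, 264 were called, 148 higher and 116 lower in Ly6D+ CLP; 1809 had an unadjusted p under 0.05, and 29 of the called genes were at the floor in both groups. With only these 4 arrays in the fit, 1 gene was called and none of the genes named here. The count for single probe sets that follows is of 34945 probe sets, not of 18193 genes. The count was 414 for single probe sets and 102 with array weights, and 1048, 932, 1144 and 694 without Ly6D- array 1, Ly6D- array 2, Ly6D+ array 1 and Ly6D+ array 2, where the lone array left in a group is assumed to vary like those of the other groups. The larger share changed sides between settings: 203 were higher and 211 lower for single probe sets, 41 and 61 with array weights, 436 and 612 without Ly6D- array 1 and 217 and 715 without Ly6D- array 2, against 833 and 311 without Ly6D+ array 1 and 514 and 180 without Ly6D+ array 2.

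Of 26 early B lineage and pre-B receptor genes, 12 rose and none fell (camera adjusted p = 2.39e-18, limma); adjusted over the list alone, 13 rose. Of 27 genes described as activated by Pax5, 6 rose and none fell, and 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 4.49e-08; adjusted p = 0.0566 with an estimated correlation). Ebf1, a transcription factor that specifies the B lineage, rose by 5.64 (SE 0.50, limma adjusted p = 0.000888) and Slamf6, a lymphocyte surface receptor, by 3.64 (SE 0.51, limma adjusted p = 0.00962). The Slamf6 call ended with averaged probe sets (2.15, adjusted p = 0.206) and with array weights (adjusted p = 0.243). Of 17 pre-B and light chain genes, Rag1 and Spib rose, and 4 rose adjusted over the list alone. That list's camera adjusted p was 0.0232, with adjusted p = 0.349 with an estimated correlation, 0.0673 by fry, and 0.213, 0.127 and 0.0554 without Ly6D- array 2, Ly6D+ array 1 and Ly6D+ array 2. Rag1, a recombinase subunit, rose by 4.15 (SE 0.80, limma adjusted p = 0.0482), and its call ended without any of the 4 arrays (0.0524 to 0.0988) and with the replicate block (0.0612). Of 37 cell cycle genes none was called over all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.353 with an estimated correlation, 0.154 by fry, 0.155 without Ly6D- array 2 and 0.0515 without Ly6D+ array 2). Its largest difference was that of Aurka, a mitotic kinase, at 1.73 (SE 0.44, limma adjusted p = 0.13; 0.00172 without Ly6D- array 1).

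Of 20 stem and multipotent progenitor genes, Mycn, Cd34 and Lmo2 fell and none rose (camera adjusted p = 1.36e-06); adjusted over the list alone, 5 fell. Mycn, a growth-promoting transcription factor, fell by 2.54 (SE 0.30, limma adjusted p = 0.00372; 0.0518 with array weights). With an estimated correlation, the early B lineage list and this list both had an adjusted p of 0.0405. Of 16 genes described as repressed by Pax5 none was called, over all genes or adjusted over the list alone (camera adjusted p = 0.00904; adjusted p = 0.0566 with an estimated correlation, 0.126 with averaged probe sets, 0.308 without Ly6D- array 2 and 0.0684 without Ly6D+ array 2). Of 15 dendritic cell genes, Pacsin1 fell by 2.52 (SE 0.32, limma adjusted p = 0.00502; 0.138 with array weights), also adjusted over the list alone. The list's camera adjusted p was 0.00904, with adjusted p = 0.0566 with an estimated correlation and 0.0644, 0.213 and 0.0800 without Ly6D- array 1, Ly6D- array 2 and Ly6D+ array 2. Of 23 granulocyte and monocyte genes, Csf3r fell by 2.79 (limma adjusted p = 0.0211), also adjusted over the list alone. That list's camera adjusted p was 0.00151, with adjusted p = 0.349 with an estimated correlation, 0.132 by fry, 0.376 without Ly6D- array 2 and 0.0872 without Ly6D+ array 1. The granulocyte transcripts S100a8 and Camp differed between the 2 Ly6D- arrays, with 10.59 and 9.28 on array 2 against 2.39 and 2.36 on array 1, while Mpo read 12.38 on array 1 and 12.12 on array 2.

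The other 11 lists did not pass camera at this step, at adjusted p of 0.715 for B cell maturation, 0.168 each for T lineage, plasma cell, IL-7 signalling, glycolysis and immediate early genes, 0.616 for NK, 0.373 for erythroid, 0.116 for interferon response, 0.504 for ribosomal and 0.969 for stromal genes. The plasma cell list was called by fry (adjusted p = 0.0247). Their called members were Ccr7, a chemokine receptor, Mzb1, a chaperone of antibody assembly, Ccnd3, a cyclin, Gata1, an erythroid factor, and Hk2, a hexokinase. Mzb1 rose by 4.06 (SE 0.43, limma adjusted p = 0.00238) and Ccnd3 by 2.82 (SE 0.43, limma adjusted p = 0.0155); averaging the Ccnd3 probe sets gave 0.74 (adjusted p = 0.0982). Ccr7 rose by 2.72 (limma adjusted p = 0.0471; 0.0797 without Ly6D- array 2 and 0.124 without Ly6D+ array 2, 0.0527 with the replicate block), and Gata1 by 1.42 (limma adjusted p = 0.0334), which was lost without Ly6D- array 1 or 2 or Ly6D+ array 2 (0.0516 to 0.0940). Hk2 fell by 2.19 (SE 0.37, limma adjusted p = 0.0248; 0.0561 without Ly6D+ array 2). Adjusted over the list alone these genes were called as well, and 1 NK gene fell.

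List members with the largest differences that were not called included Prtn3, a granulocyte protease (-3.93, limma adjusted p = 0.188), Camp, a granule peptide (-3.46, limma adjusted p = 0.494), Oasl2, an interferon response gene (-3.93, limma adjusted p = 0.171), Ccr9 (-3.00, limma adjusted p = 0.222), Nfil3 (-2.25, limma adjusted p = 0.0814) and Hoxa9 (-2.00, limma adjusted p = 0.568). Hes1 (2.09), Irf4 (2.02), Slc16a1 (1.98), Nusap1 (1.55) and Socs3 (1.05) were not called, at limma adjusted p between 0.251 and 0.584. Neither were Ier3 (-1.89), Cd74 (-1.88), Hspa1b (-1.73), Tox (-1.72), Car2 (-1.70), Ccl3 (-1.66), Vcam1 (-1.58), Cd33 (-1.50), Cd5 (-1.44) and Irf7 (-1.07), at limma adjusted p between 0.149 and 0.697, nor Pecam1 (-0.67), Rpl12 (-0.49) and Rpl14 (0.42), at 0.867 to 1. Without Ly6D- array 1, Camp (0.000289), Nfil3 (0.0248) and Nusap1 (0.0213) were called, without Ly6D- array 2 Tox (0.0351) and Ier3 (0.00495), without Ly6D+ array 1 Oasl2 (0.00186), and without Ly6D+ array 2 Irf4 (0.00458) and Cd33 (0.0417), with the limma adjusted p in parentheses. Nfil3 was also called without dim genes (0.0365) and without genes at the floor (0.0339), Prtn3 with the Xist term (0.0289) and Ccr9 with averaged probe sets (-1.01, adjusted p = 0.0493). Array weights ended the calls of Rag1, Spib, Ccnd3, Ccr7, Gata1, Hk2, Hsd3b7 and Sh2b2 as well (limma adjusted p from 0.0527 to 0.697). The Ccr7 call also ended for single probe sets (0.0538), after quantile normalization (0.0675) and with the Xist term (0.0634), that of Rag1 for single probe sets (0.0553) and that of Sh2b2 with the Xist term (0.0510). The term left the changes of Ccr7 and Sh2b2 as they were, at 2.72 and -4.62.

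The comparison of ProB with Ly6D+ CLP followed the second step. Pax5 read 4.41 ± 0.69 in ProB and 4.79 ± 1.96 (SD, n = 2 each) in Ly6D+ CLP, a difference of -0.38 (SE 0.73, limma adjusted p = 0.998), which was 1.0 (adjusted p = 0.193) without Ly6D+ array 1, 0.11 (adjusted p = 1) without ProB array 1 and -1.76 (adjusted p = 0.0356) without Ly6D+ array 2. Jchain rose by 9.54 (SE 1.77, limma adjusted p = 0.0138; 0.0625 without ProB array 2), Igkv8-30, a light chain variable segment, by 8.77 (SE 0.88), Igha, the IgA heavy chain, by 8.54 (SE 1.18) and Ighg3, the IgG3 heavy chain, by 7.43 (SE 0.49). Igha read 11.93 ± 0.03 in ProB and 3.38 ± 0.44 (SD, n = 2 each) in Ly6D+ CLP. Enpep, the aminopeptidase BP-1 of early B cells, rose by 6.41 (SE 0.11, limma adjusted p = 3.84e-08) and Bcat1, a transaminase of branched-chain amino acids, by 6.33 (SE 0.31).

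Cd34, a marker of stem and progenitor cells, fell from 10.07 ± 0.88 (SD, n = 2) to the floor, by 7.75 (SE 0.31, limma adjusted p = 6.91e-06). Large falls were also those of Gm4047 (-7.72, SE 0.17), Mpo, the myeloperoxidase of granulocyte precursors (-7.64, SE 1.32), Mpeg1, a pore-forming protein of macrophages (-7.63, SE 0.54), Pdgfrb, a growth factor receptor (-7.43, SE 0.45), and Ptger2, a prostaglandin receptor (-6.90, SE 0.70). Flt3 fell by 6.55 (SE 0.40, limma adjusted p = 9.12e-05) and Ly6d fell by 4.99 (SE 0.55, limma adjusted p = 0.00121). Igll1 and Ptprc differed by 0.81 (SE 0.44, limma adjusted p = 0.330) and -1.44 (SE 0.55, limma adjusted p = 0.204).

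Of 18193 genes, 1327 were called, 351 higher and 976 lower in ProB cells. An unadjusted p under 0.05 was found for 3232, and 41 of the called genes were at the floor in both groups. After quantile normalization 496 were higher and 755 lower, and without ProB array 1 the larger share changed sides, with 1338 higher and 791 lower. With only these 4 arrays in the fit, 3 genes were called, of which Cd22 and Ms4a1 are named here. The count was 368 with array weights and 693 with a term for arrays with high Xist. That transcript read 10.71 and 11.49 in ProB and 2.33 on both Ly6D+ CLP arrays, so these arrays cannot set the term. The sex of the cells thus differed between ProB and Ly6D+ CLP on every array and cannot be told apart from the stage.

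Of 20 stem and multipotent progenitor genes, 10 fell and none rose (camera adjusted p = 7.7e-10, limma); adjusted over the list alone, 12 fell. Of 16 genes described as repressed by Pax5, 8 fell, Flt3 among them, and Jchain rose; 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 4.58e-07). Of 15 dendritic cell genes, 6 fell and none rose, and 7 fell adjusted over the list alone (camera adjusted p = 0.00109). Ccr9, a chemokine receptor, fell by 4.39 (SE 0.92, limma adjusted p = 0.0230), lost without ProB array 1 or 2 or Ly6D+ array 2 (0.0595 to 0.0977). In the plasma cell list of 10 genes, Jchain, Irf4 and Tnfrsf17 were called higher and none lower, Tnfrsf17 with both groups at the floor; 4 were higher adjusted over the list alone (camera adjusted p = 0.00259). Irf4, a transcription factor of activated B cells, rose by 4.50 (SE 0.81, limma adjusted p = 0.0121; 0.0613 without ProB array 2). With an estimated correlation these 4 lists had adjusted p of 0.0107, 0.00790, 0.0321 and 0.0413, in order.

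Of 27 genes described as activated by Pax5, 10 rose and 1, Irf8, fell, with the same counts adjusted over the list alone (camera adjusted p = 1.14e-06; adjusted p = 0.0789 with an estimated correlation). Cd22, an inhibitory receptor of B cells, rose by 5.71 (SE 0.48, limma adjusted p = 0.000408), and Srpk3 by 5.19 (SE 1.12, limma adjusted p = 0.0268), a call lost without ProB array 2 or either Ly6D+ array (0.0648 to 0.134). Of 37 cell cycle genes, 8 rose and none fell, and 15 rose adjusted over the list alone (camera adjusted p = 4.12e-10; adjusted p = 0.0789 with an estimated correlation). Plk1, a mitotic kinase, rose by 3.35 (SE 0.32, limma adjusted p = 0.000676) and Tpx2, a spindle protein, by 2.67 (SE 0.35). Of 18 interferon response genes, 6 fell and none rose, and 10 fell adjusted over the list alone (camera adjusted p = 8.73e-05; adjusted p = 0.0789 with an estimated correlation). Rsad2, the antiviral protein viperin, fell by 3.93 (SE 0.64, limma adjusted p = 0.00794), and Mx1, an antiviral GTPase, fell by 4.00 (SE 0.99, limma adjusted p = 0.0461), a call that ended without any of the 4 arrays (0.107 to 0.156) and with the replicate block (0.0671). Of 23 granulocyte and monocyte genes, Mpo, Fcer1g and Cebpb fell; 5 fell adjusted over the list alone (camera adjusted p = 0.0061; adjusted p = 0.338 with an estimated correlation and 0.0521 without Ly6D+ array 2). Of 17 genes of IL-7 and cytokine signalling, Socs3, Myc and Pim1 fell, and 6 fell adjusted over the list alone. That list's camera adjusted p was 0.0183, with adjusted p = 0.175 with an estimated correlation, 0.0548 without dim genes, and 0.0528, 0.0735 and 0.148 without ProB array 1, Ly6D+ array 1 and Ly6D+ array 2. Socs3, a feedback inhibitor of cytokine receptors, fell by 5.24 (SE 0.66, limma adjusted p = 0.00216).

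The other 10 lists did not pass camera at this step. In the early B lineage list 6 rose and Rag1, Cd93, Myb and Syk fell (adjusted p = 0.343; 6 and 6 adjusted over the list alone), and in the pre-B list 6 rose and Rag1, Il10ra, Irf8, Spi1 and Btg1 fell (adjusted p = 0.339; 6 and 5 adjusted over the list alone). Fcrla rose by 6.07 (SE 0.35), Ikzf3 by 4.32 (SE 0.33) and Ms4a1 by 4.60 (SE 0.46). In the B cell maturation list Cd22, Ms4a1 and Fcmr rose and H2-DMa, which loads peptides on MHC class II, fell by 5.81 (SE 0.40), also adjusted over the list alone (adjusted p = 0.219). Of the NK list, Nkg7, Il18r1, Id2 and Klrd1 fell (adjusted p = 0.0503; 0.0322 without Ly6D+ array 2, 0.0355 with averaged probe sets, 0.0170 after quantile normalization and 0.00205 by fry), and of the T lineage list Notch1, the receptor of T cell commitment (-4.10, SE 0.23), and Cd247 (-3.93, SE 0.37) (adjusted p = 0.226; 0.00421 by fry), with the same counts adjusted over the list alone. In the immediate early list Hspa1b, an inducible heat shock protein, rose by 5.20 (SE 1.02) and Junb, Btg2 and Klf2 fell (adjusted p = 0.0814, with 0.0319 with averaged probe sets and 0.00563 by fry; 1 and 4 adjusted over the list alone); the Hspa1b call ended without ProB array 2 or either Ly6D+ array (0.0524 to 0.0888). In the ribosomal list Rpl12 and Rpl7 fell, and 4 fell adjusted over the list alone (adjusted p = 0.0547; 0.0491 with averaged probe sets, 0.000148 without ProB array 2 and 0.835 in the opposite direction after quantile normalization); Rpl12 fell by 3.02 (SE 0.53; limma adjusted p = 0.0538 without ProB array 2). In the glycolysis list Txnip and Slc2a3 fell (adjusted p = 0.254; 2 fell and 1 rose adjusted over the list alone), and the call of Txnip, which fell by 2.25, ended without any of the 4 arrays (0.0506 to 0.121). In the erythroid list Gata1 fell by 1.42 (list adjusted p = 0.628), lost without ProB array 2 or Ly6D+ array 2 (0.0518 and 0.0526). In the stromal list Pdgfrb fell and Sparc, a matrix protein, rose by 1.39 (list adjusted p = 0.628 and 0.0434 by fry). Averaging the Sparc probe sets gave 0.46, which was not called. The counts of these last 2 lists were the same adjusted over the list alone.

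List members with the largest differences that were not called were Pfkp (2.20, limma adjusted p = 0.0793; 0.00478 without Ly6D+ array 2 and 0.0344 without dim genes), Car2 (1.24, limma adjusted p = 0.309), Rpl19 (-1.02, limma adjusted p = 0.0994; 0.0472 with the Xist term) and Tyrobp, a signalling adaptor of myeloid and NK cells (-3.70, limma adjusted p = 0.0735; 0.0286 without dim genes and 0.0246 without genes at the floor). Array weights ended the calls of Jchain, Igha, Hspa1b, Srpk3, Gata1, Txnip, Rpl12, Myc, Rsad2, Mx1, Ccr9, Nkg7, Ptger2 and Mpo (limma adjusted p from 0.0507 to 0.405). The term for arrays with high Xist ended those of Jchain, Igha, Hspa1b, Srpk3, Irf4, Tpx2, Txnip, Rpl12, Rsad2, Mx1, Ccr9, Il18r1 and Socs3 (limma adjusted p from 0.0572 to 0.601). The term was set by the difference of WT engrafted array 3 from the other WT engrafted arrays, not by ProB or Ly6D+ CLP. Under the term, Rpl12, Mx1 and Rsad2 were at 61.6%, 65.5% and 75.3% of their changes without it. The other 10 genes were at 81.0% to 115%. The SE of the 13 genes was 1.34 to 1.68 times as large. Averaged probe sets ended the calls of Srpk3 (0.0540), Sparc (0.0696) and Txnip (0.170), and single probe sets that of Mx1 (0.0603).

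The comparison of PreB with ProB followed the third step. Pax5 read 5.01 on both PreB arrays and 4.41 ± 0.69 (SD, n = 2) in ProB, a difference of 0.59 (SE 0.73, limma adjusted p = 0.809). Transcripts of granulocytes and NK cells were among the largest rises in PreB cells. S100a8 and S100a9, the calprotectin subunits of neutrophils, rose by 9.20 (SE 2.10, limma adjusted p = 0.0240) and 8.43 (SE 1.67, limma adjusted p = 0.0133), Ngp, a neutrophil granule protein, by 8.91 (SE 1.67, limma adjusted p = 0.0105), and Chil3, a chitinase-like protein of myeloid cells, by 8.34 (SE 1.40). Gzma, a granzyme of cytotoxic lymphocytes, rose from the floor to 10.63 ± 0.45 (SD, n = 2), by 8.22 (SE 0.25, limma adjusted p = 3.9e-07). The S100a8 call ended when any of the 4 arrays was left out (0.0683 to 0.106), that of Ngp without PreB array 3 (0.0541) and that of S100a9 without PreB array 3 or ProB array 2 (0.0654 and 0.0511). Eif2s3y, a Y-linked gene, rose by 8.71 (SE 2.3, limma adjusted p = 0.0438). Its call ended without any of the 4 arrays, with changes between 8.69 and 8.72, and with the replicate block (limma adjusted p = 0.0658). Eif2s3y was at the floor on both ProB arrays, where Xist was high, and Xist was low on both PreB arrays. The sex of the cells thus differed between these groups on every array and cannot be told apart from the stage.

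Among the largest falls were those of 3 transcripts that had risen at the step before. Ighg3 fell by 7.40 (SE 0.49, limma adjusted p = 5.37e-05), Jchain fell by 6.50 (SE 1.77, limma adjusted p = 0.0488) and Igha fell by 6.19 (SE 1.18, limma adjusted p = 0.0111). The Jchain call ended without PreB array 3 (-3.48, adjusted p = 0.181), ProB array 1 (0.113) or ProB array 2 (0.172), and that of Igha without ProB array 2 (0.0532). Plk1 fell by 5.25 (SE 0.32, limma adjusted p = 3.27e-05), Klhl32 fell by 5.24 (SE 0.41) and Ada, adenosine deaminase, fell by 5.03 (SE 0.43). Igll1 fell from 13.20 ± 0.38 to 8.71 ± 0.44 (SD, n = 2 each), by 4.49 (SE 0.44, limma adjusted p = 0.000433). Ly6d rose by 2.99 (SE 0.55, limma adjusted p = 0.00972) and Ptprc by 2.29 (SE 0.55, limma adjusted p = 0.0304); the Ptprc call ended without any of the 4 arrays (0.0669 to 0.137).

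Of 18193 genes, 2100 were called, 1156 higher and 944 lower in PreB cells. An unadjusted p under 0.05 was found for 3955, and 60 of the called genes were at the floor in both groups. The larger share changed sides after quantile normalization (1051 higher and 1179 lower) and without ProB array 1 (868 higher and 1827 lower). The count was 487 with only these 4 arrays and 746 with a term for arrays with high Xist, which these arrays cannot set. The actin probe sets differed more between the 3' and 5' ends in PreB (7.27 and 6.71 on the log2 scale) than in ProB (2.73 and 3.67), a measure of RNA quality.

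Of 17 pre-B and light chain genes, 11 rose and none fell (camera adjusted p = 2.12e-11, limma); adjusted over the list alone, 13 rose. Cd2 rose by 7.09 (SE 0.37, limma adjusted p = 1.21e-05) and Cxcr4, a receptor that holds cells in the marrow, by 4.23 (SE 0.48, limma adjusted p = 0.000966). Of 20 immediate early and stress genes, 12 rose and none fell, and 15 rose adjusted over the list alone (camera adjusted p = 2.7e-12). Hspa1a, an inducible heat shock protein, rose from the floor to 10.07 ± 0.12 (SD, n = 2), by 7.55 (SE 0.23, limma adjusted p = 4.64e-07), and Hspa1b rose by 5.80 (SE 1.02). Of 16 NK and innate lymphoid genes, 9 rose and none fell, and 10 rose adjusted over the list alone (camera adjusted p = 9.95e-11); Id2, a transcription regulator that opposes the B lineage program, rose by 7.96 (SE 0.46, limma adjusted p = 2.37e-05). Of 23 granulocyte and monocyte genes, 12 rose and none fell, and 16 rose adjusted over the list alone (camera adjusted p = 1.15e-10). Of 16 genes described as repressed by Pax5, 5 rose, namely Csf1r, Fcer1g, Sla, Siglech and Ccr2, and Jchain and Ramp1 fell; 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.00124). Csf1r, the macrophage growth factor receptor, rose by 4.91 (SE 1.05, limma adjusted p = 0.0186), lost without PreB array 2 or 3 or ProB array 2 (0.0583 to 0.0879) and with averaged probe sets (0.0594). Csf1r and Fcer1g also stand in the granulocyte list. With an estimated correlation these 5 lists had adjusted p of 0.0136, 0.00872, 0.00872, 0.0461 and 0.0279, in order.

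Of 37 cell cycle genes, 18 fell and none rose, and 23 fell adjusted over the list alone (camera adjusted p = 2.7e-12; adjusted p = 0.0611 with an estimated correlation). Aurka, a mitotic kinase, fell by 3.27 (SE 0.44, limma adjusted p = 0.00227). Of 19 genes of B cell maturation, 7 rose and none fell, and 11 rose adjusted over the list alone (camera adjusted p = 3.54e-07; adjusted p = 0.0687 with an estimated correlation); Cd83, a surface protein of mature B cells, rose by 6.64 (SE 0.55, limma adjusted p = 0.000189). Of 27 genes described as activated by Pax5, 9 rose and none fell, and 11 rose adjusted over the list alone (camera adjusted p = 1.21e-05; adjusted p = 0.0883 with an estimated correlation); Cd55, a regulator of complement, rose by 4.96 (SE 0.33, limma adjusted p = 5.46e-05), and Tnfrsf13c, the receptor of the survival factor BAFF, by 3.95 (SE 0.85, limma adjusted p = 0.0186), a call that ended without any of the 4 arrays (0.0550 to 0.0825). Of 26 early B lineage genes, 9 rose, with Fcrla by 4.62 (SE 0.35), and Igll1, Vpreb1, Bcl11a and Dntt fell; 12 rose and 5 fell adjusted over the list alone. That list's camera adjusted p was 0.0292, with adjusted p = 0.499 with an estimated correlation, 0.0887 with averaged probe sets, 0.0827 without dim genes, 0.0807 without genes at the floor, and 0.0957, 0.105 and 0.0697 without PreB array 2, PreB array 3 and ProB array 1. Of 16 erythroid and megakaryocyte genes, Ermap and Rhag rose and none fell, also adjusted over the list alone. That list's camera adjusted p was 0.0187, with adjusted p = 0.0687 with an estimated correlation, 0.0543 without dim genes, 0.0956 without PreB array 3 and 0.0514 without ProB array 2.

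The other 9 lists did not pass camera at this step. In the glycolysis list 7 fell and Slc2a3 and Txnip rose, and 8 fell and 3 rose adjusted over the list alone (adjusted p = 0.0560; 0.0459 with the replicate block, 0.0314 after quantile normalization, 0.0476 without genes at the floor and 0.00204 by fry); Ldha, which makes lactate, fell by 3.22 (SE 0.49, limma adjusted p = 0.00396) and Pfkl, a phosphofructokinase, fell by 3.09 (SE 0.56, limma adjusted p = 0.00914; 0.0508 without ProB array 2). In the IL-7 list 6 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.456), and the falls were those of Ccnd3, Ccnd2 and Myc; Socs3 rose by 6.09 (SE 0.66) and Ccnd3 fell by 4.25 (SE 0.43). In the dendritic list Ccr9, Irf8 and Siglech rose, also adjusted over the list alone (adjusted p = 0.0597; 0.00261 without PreB array 3, 0.0351 with averaged probe sets and 3.96e-05 by fry); Ccr9 rose by 7.49 (SE 0.92, limma adjusted p = 0.00141). In the T lineage list Dtx1 rose by 4.55 (SE 0.23) and Lat, an adaptor of the T cell receptor, fell by 2.67 (adjusted p = 0.279 and 0.0162 by fry); the Lat call ended without PreB array 2 or either ProB array (0.0644 to 0.113). In the stem cell list Sox4 and Mycn rose and Erg and Egfl7 fell (adjusted p = 0.733; 3 and 3 adjusted over the list alone). Egfl7 fell by 3.75 (SE 0.44) and Erg fell by 3.99 (SE 0.84; lost without PreB array 3 or ProB array 2, 0.0899 and 0.103). In the plasma cell list Prdm1 was called higher and Jchain and Tnfrsf17 lower, Tnfrsf17 with both groups at the floor (adjusted p = 0.456; 3 and 3 adjusted over the list alone). In the interferon list Rsad2 rose by 3.74 (SE 0.64) and Oas1a and Usp18 fell (adjusted p = 0.144; 2 and 5 adjusted over the list alone). In the ribosomal list Rpl12 rose by 2.12 and Rpl11 and Rpl8 fell (adjusted p = 0.0748; 0.00289 after quantile normalization, 0.0272 with averaged probe sets and 0.0244 without ProB array 1; 2 and 5 adjusted over the list alone); the Rpl12 call ended without any of the 4 arrays (0.0848 to 0.143) and with the replicate block (0.0549). In the stromal list Vcam1, an adhesion molecule, rose by 3.07 (lost without PreB array 2 or ProB array 2, 0.0648 and 0.0599) and Sparc fell by 1.10 (list adjusted p = 0.456; 0.0110 without PreB array 2). Averaging the Sparc probe sets gave 0.15 (adjusted p = 0.597), in the opposite direction. The T lineage and stromal counts were the same adjusted over the list alone.

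List members with the largest differences that were not called were H2-Aa, an MHC class II chain (4.67, limma adjusted p = 0.0611), Ell2 (2.78, limma adjusted p = 0.137), Rpl14 (-1.88, limma adjusted p = 0.0863), and the platelet transcripts Pf4 (3.99) and Ppbp (3.25), both with a limma adjusted p of 0.272. H2-Aa was called with averaged probe sets (4.24, adjusted p = 0.0116), without dim genes (0.0226) and without genes at the floor (0.0195). Rpl14 was called without dim genes (0.0399) and without genes at the floor (0.0370). Pf4 and Ppbp were high on PreB array 3 alone, so their calls without PreB array 2 rest on a single array and on a spread taken from arrays near the floor. Array weights ended the calls of Eif2s3y, Csf1r, Rsad2, Ptprc, Rpl12, Lat, Erg and Jchain (limma adjusted p from 0.0559 to 0.175). The term for arrays with high Xist ended those of S100a8, S100a9, Ngp, Chil3, Eif2s3y, Hspa1b, Csf1r, Tnfrsf13c, Rsad2, Ly6d, Ptprc, Rpl12, Siglech, Sparc, Lat, Oas1a, Pfkl, Igha and Jchain (limma adjusted p from 0.0819 to 0.764). Xist was high on both ProB arrays and low on both PreB arrays, so the term again came from the WT engrafted arrays alone. Under the term Eif2s3y was at 0.53 (SE 0.42), and Ptprc and Rpl12 were at 44.2% and 45.4% of their changes without it. The other 16 genes, S100a8 (10.15, SE 3.50) and S100a9 (9.70, SE 2.75) among them, were at 69.1% to 132%. Their SE was 1.49 to 1.68 times as large. With only these 4 arrays in the fit, the calls of Fcrla, Cxcr4, Tnfrsf13c, Rsad2, Vcam1, Ly6d, Ptprc, Siglech, Sparc, Lat, Oas1a, Pfkl, Ldha, Egfl7, Erg, Ccnd3, Igll1, Igha and Jchain ended (limma adjusted p from 0.0630 to 0.409). Averaged probe sets ended that of Vcam1 (0.0841), and single probe sets those of Eif2s3y (0.0535) and Jchain (0.0594).

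**Figure D4:**
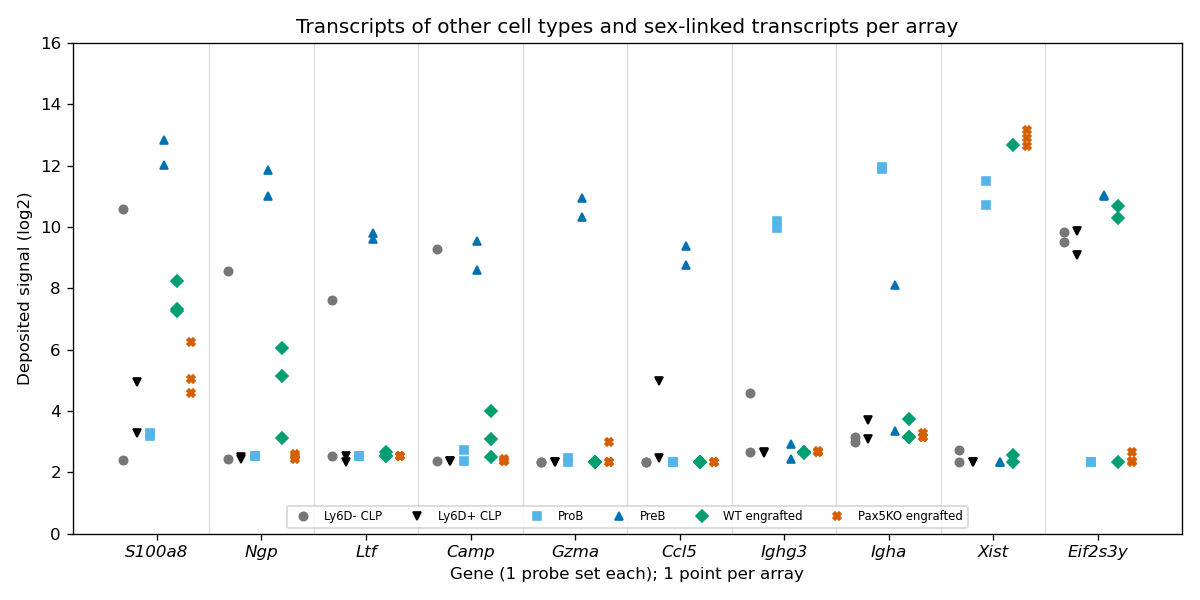
Deposited log2 signal (vertical axis) of granulocyte, NK cell, antibody and sex-linked transcripts (horizontal axis), with 1 point per array and a symbol per group. S100a8 read 12.02 and 12.85 on the PreB arrays and 10.59 on Ly6D- CLP array 2, and Igha 11.91 and 11.95 on the ProB arrays.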

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

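The splits of the engrafted arrays and the test on the sex chromosomes were written down before their results were seen; the look at probe sets without a single gene symbol was chosen after the data were seen.

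Probe sets with several gene symbols or with none entered no comparison of the report. Of 10092 such probe sets, 145 passed an adjusted p of 0.05 in limma between Pax5KO and WT engrafted cells, 64 higher and 81 lower in Pax5KO cells. That is 1.44% of them, against 3.75% of the probe sets with 1 symbol. This signal in data outside the main measurement is given as a count only, since the probe sets cannot be assigned to a gene here.

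Of the genes called between Pax5KO and WT engrafted cells, 1080 in the real grouping, 1 of the 10 splits of the 6 arrays gave as many, and the highest other split gave 1 gene. For the fixed lists the real grouping gave 13, 1 of the splits gave as many, and the highest other split gave 7. For the stage lists the real grouping gave 4, 7 of the 10 splits gave as many, and the highest other split gave 5. With 10 splits no share can lie under 0.05. Among the 4 splits that part all same-numbered pairs, the 3 others called no gene, at most 7 lists and at most 4 stage lists. In the other splits the median of the ProB rise list was at most 0.59 in size and that of the fall list at most 0.85, against -1.04 and 2.05 in the real grouping. Each other split mixed both genotypes on each side, so part of any genotype difference entered the spread within groups. Smaller gene counts and medians there follow from that mixing and decide nothing about chance.

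Xist was high on the 3 Pax5KO arrays and on WT array 3, and low on WT arrays 1 and 2, so the sex of the cells was weighed as an explanation of the called genes. Of the 1080 called genes, 21 lie on X or Y, which is 1.94%, against 3.55% of the other genes (Fisher's exact p = 0.0034). Few of the called genes are thus transcripts of the sex chromosomes. The WT group held arrays with high and with low Xist, so sex-linked genes varied widely within it and were hard to call. The low share therefore decides nothing about sex as an explanation. Over the 1034 genes called without WT array 3, that array lay at a median position of 0.167 between the other WT arrays (0) and the Pax5KO mean (1), with quartiles of -0.01 and 0.467. Effects of sex on genes of other chromosomes stay open. A term for high Xist leaves the Pax5KO mean against WT array 3 alone here, so it cannot settle them. The genotype is the biological difference that the design names, and it was not separated from sex in the WT group beyond array 3.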

How the results depend on the processing

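Leaving out genes at the floor, leaving out both arrays numbered 3, the term for high Xist and stage lists without other cell types were chosen after the data were seen.

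Named genes kept their direction and side of the threshold in 2576 tests under alternatives; 283 lost the call, 50 gained it, 12 differences without a call changed sign or went to 0 and 1 called change reversed. For the fixed lists these were 777, 73, 27, 16 and 0, and for the stage lists 79 kept, 3 gained and 2 changed sign. The reversal was that of Sparc between PreB and ProB with averaged probe sets, at 0.15 (adjusted p = 0.597). Its 3 probe sets ran from -1.10 to 1.14, so averaging them changed the sign. Why they differed, and the causes of the lost and gained calls, were not tested.

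For Pax5KO against WT engrafted cells, 697 genes were called with only the 2 groups fitted, 3065 with array weights, and 676 to 1034 without 1 array; the lists fell from 13 to 4 with an estimated correlation. For Ly6D+ against Ly6D- CLP, 1 gene was called with only the 2 groups fitted, where fewer arrays give the variance, 414 for single probe sets, 102 with array weights and 694 to 1144 without 1 array; the lists were 2 with an estimated correlation and 3 to 7 without 1 array. For ProB against Ly6D+ CLP, 3 genes were called with only the 2 groups fitted, 368 with array weights, 693 with the term for high Xist and 1060 to 2129 without 1 array, and 4 lists with an estimated correlation. For PreB against ProB, 487 were called with only the 2 groups fitted and 746 with the term for high Xist, and 5 lists with an estimated correlation. Where 1 array is left in a group, it is assumed to vary like the other groups. The term for high Xist was set by the WT engrafted arrays alone. The cause was not tested for the other alternatives.

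The stage lists called numbered 4 or 5 under the alternatives run, and the stage score difference ran from -5.29 with 50 genes to -1.63 with all called genes, each with an exact permutation p of 0.1.

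With the replicate number as a block, 1108, 368, 1393 and 2008 genes were called in the 4 comparisons, of which 916, 251, 1230 and 1884 were also called without it. The block changed the call of Rpl14, Pecam1, Rag1, Ccr7, Mx1, Eif2s3y, Rpl12 and the glycolysis list, as given in the report, and of no other named gene or list. Among the groups without transplant, same-numbered arrays correlated across genes with r of 0.00932, -0.0458 and 0.105, in order of the comparisons, with PreB and ProB paired by the description numbers; by the title numbers, the r of PreB and ProB arrays 2 was -0.105. The scaling alternatives moved the median of all genes by less than 0.1. The floor limits what can be measured: 5927 of 18193 genes lay within 0.5 of it on all arrays.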

Other observations

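The tests on granulocytes, RNA quality, plasma cells and Ighm were chosen after the results they concern were seen.

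Several granulocyte transcripts were high on Ly6D- CLP array 2 and near the floor on array 1 of the group, among them Ngp, Ltf and Chil3: Ngp read 8.58 against 2.45, Ltf 7.61 against 2.55 and Chil3 7.48 against 2.33. On PreB array 3 the platelet transcripts Pf4 and Ppbp read 10.31 and 8.81, and both were at the floor on PreB array 2. PreB array 2 held Igha at 8.12 and Jchain at 8.64, against 3.36 and 2.59 on PreB array 3. Eomes, a transcription factor of NK cells, read 8.76 and 8.87 on the PreB arrays and Ccl5, a chemokine, 8.77 and 9.37.

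Jchain read between 11.78 and 12.54 on the Pax5KO arrays, where Igha was between 3.14 and 3.28 and Ighg3 between 2.66 and 2.70. The Y-linked Eif2s3y was high on both PreB arrays, the 4 CLP arrays and WT engrafted arrays 1 and 2 (9.08 to 11.04), and low where Xist was high.

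Granulocyte transcripts were higher in PreB than in ProB cells, and granulocytes in the sorted sample may be a source. Across the 23 genes of the granulocyte list, the PreB minus ProB difference correlated with the difference between Ly6D- CLP arrays 2 and 1 with a Pearson r of 0.831 and a Spearman rho of 0.476; genes are not independent replicates. S100a8, S100a9 and Ngp read between 11.03 and 12.85 on the PreB arrays. Of these list genes, 1 had a mean above 5 in ProB, 8 in Ly6D+ CLP, and 2 stand in another list. A gate on B lineage markers would remove such cells, but no gates are stated for these samples.

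Uneven RNA quality was weighed for the granulocyte and NK transcripts, since actin 3' to 5' differences were largest in PreB (7.27 and 6.71, and at most 5.57 on other arrays). The Gapdh differences were largest on Pax5KO array 3 and WT array 3 (5.79 and 5.44), above PreB (4.88 and 4.35). Eomes was at the floor on these 2 arrays and Gzma read 3.0 and 2.32, against 8.76 to 10.95 for both on the PreB arrays. Over the 21 called genes of both lists the median change was 4.33, and on 3 arrays with a higher ratio than the rest of their groups the median difference from the other arrays of their groups was 0.0690 (0.24 on Pax5KO array 3, 0.34 on WT array 3 and 0 on Ly6D+ CLP array 2). In 29 of these 63 differences, though, every array of the group was at the floor, and a gene without signal cannot show an effect of RNA quality. The median of the others was 0.714 (quartiles 0.242 and 1.39). RNA quality therefore cannot be told apart from other sources, because the genes at the floor decide nothing, the others varied widely, and no other array had an actin difference as large as those of PreB. Of the 16 NK list genes, none had a mean above 5 in ProB and 4 did in Ly6D+ CLP. No biological explanation other than granulocytes in the sorted sample was tested for these transcripts.

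Igha, Ighg3 and Jchain were higher in ProB than in Ly6D+ CLP and PreB, and plasma cells in the ProB samples could be a source. Of the 9 plasma cell list genes other than Jchain, 1 was higher in ProB against both groups, Tnfrsf17, which was near the floor. Prdm1 was at the floor in ProB and in Ly6D+ CLP, while Irf4 was higher in ProB than in Ly6D+ CLP by 4.50. Of the 10 list genes, 7 had a mean above 5 in ProB and 4 in Ly6D+ CLP. These values go both ways, so plasma cells cannot be told apart from other sources. Probe sets that also read Ighm were weighed too, but Ighm was higher in PreB than in ProB by 1.47 (SE 0.30, limma adjusted p = 0.0158), which argues against them.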
